A study of Homo sapiens with 12 samples.

How the data were processed

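RNA from 12 samples of the human lung adenocarcinoma line A549 was profiled on 1-colour Affymetrix expression arrays, 1 array per sample. Per the labels' protocols, biotin-labelled cRNA was made from 2 ug of total RNA by the manufacturer's standard procedure. The labels place 4 arrays in each of 3 groups. These are untransduced wild type cells, cells transduced with lentiviral vectors carrying siRNA sequences against both ALDH1A1 and ALDH3A1 (ALDH siRNA group), and cells transduced with a vector carrying siRNA against green fluorescent protein (GFP siRNA group). Arrays were numbered by the clone number in the labels. The source names call the arrays of each group separate clones, numbered 1 to 4, but the titles of ALDH siRNA replicates 1 to 4 are Clone 1A, Clone 1B, Clone 2 and Clone 5. The titles thus name 3 clone numbers where the source names give 4. The replicate block and the pairing check used the source names' numbers. Nothing states whether these came from separate clonal isolates or whether wild type clones were separate cultures, so p-values measure only the spread between these samples.

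The authors deposited a linear signal intensity for each of 54675 probe sets, with no missing value and between 1 and 6 exact zeros per array. The method that summarised the probes, the background correction and the scaling are not given in the sources used here. The authors also deposited a text sheet of genes under headings for up and down regulation, with a cytogenetic band for most. It states neither the groups compared nor a threshold. Probe set identifiers were not paired with gene names in the sources used here, so the tests were run per probe set. The planned steps that need gene names were not run. These were the level of the 2 targeted genes, the tests of 35 gene lists, the choice of 1 probe set per gene and the count of called genes per chromosome. The same lists were instead set against the symbols of the authors' deposited sheet. Symbols were matched to the RefSeq gene table of GRCh38.p14, used for names and chromosomes only.

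The 62 control probe sets were set aside, which left 54613. Column medians differed by 0.391 on the log2 scale. Because that exceeded the limit of 0.3 set in advance, the intensities were quantile normalized across all 12 arrays. Values under 32 were then set to 32 and log2 was taken. Group-blind filtering kept probe sets at or above the array median on at least 4 of the 12 arrays, which left 30351. A fold change against a group lying at the floor of 32 is a lower bound. One linear model over the 3 groups was fitted with limma 3.58.1 (lmFit, contrasts, eBayes) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and a probe set was called at an adjusted p under 0.05. The number called at 2-fold or more is given beside it. Array-level control measures were compared with an exact two-sided permutation test over the 70 assignments of 4 against 4 arrays, whose smallest possible p is 0.0286. The 24 such tests were adjusted together. Membership of gene lists in the authors' deposited sheet was compared between its up and down parts with Fisher's exact test (SciPy 1.17.1). The number of arrays limits the precision of every value.

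Probe sets were named by a fixed rule. It took the 10 largest rises and 10 largest falls in ALDH siRNA against GFP siRNA cells among those called the same way against both controls, with all 4 ALDH siRNA arrays beyond all 8 control arrays. Because identifiers carry no gene names here, only the first 2 of each are printed.

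The procedure was tested on simulated data with the real probe set means and spreads, in which 29032 probe sets passed the filter. In the ALDH siRNA group 200 probe sets were changed, in equal numbers up and down. For ALDH siRNA against GFP siRNA it recovered 69% of the 1.5-fold and 85% of the 2-fold changes, with 7 false calls among 161. For ALDH siRNA against wild type it recovered 68% and 86%, with 8 false calls among 162. For GFP siRNA against wild type, where nothing was changed, it made 0 calls. The simulation had few changed probe sets and no outlying array, so it does not give the error rate where most probe sets are called.

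Sharing of calls between the 2 comparisons of ALDH siRNA cells was set against 20 simulations of unchanged groups that share the same arrays, and repeated with the ALDH siRNA arrays halved in each of 6 ways. Alternatives fixed before the data were examined were the deposited values without normalization, median centring, log2(value + 1) without a floor, no filter, a filter at the 75th percentile, removal of probe sets ending in _x_at or _s_at, a trended robust variance, array weights, fits of only the groups compared, the clone number as a replicate block, replicates 1 and 2 of the ALDH siRNA group averaged, Welch's test per probe set, and leaving out each array in turn. A fit in which GFP siRNA replicate 3 alone stood for its group was added after the data were seen.

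The clone numbers did not pair the arrays. Deviations from the group means of same-numbered arrays correlated between -0.357 and 0.246, and only 4 of the 12 pairs exceeded 0.1.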

Results

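Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, after lentiviral delivery of siRNA sequences against 2 aldehyde dehydrogenase genes. ALDH1A1 encodes an enzyme that oxidises retinaldehyde to retinoic acid, and ALDH3A1 encodes an enzyme that oxidises aromatic and medium-chain aldehydes. The series comprised 4 arrays of cells carrying both vectors (ALDH siRNA), 4 of cells carrying an siRNA against green fluorescent protein (GFP siRNA), and 4 of untransduced cells (wild type). The GFP siRNA cells are the control named by the study's design. The median deposited signal per array was 101 ± 1.90 (SD, n = 4) in wild type, 107 ± 2.27 (SD, n = 4) in ALDH siRNA and 87.6 ± 7.15 (SD, n = 4) in GFP siRNA cells. Because probe sets could not be tied to gene names, levels of ALDH1A1 and ALDH3A1 on the arrays were not analysed here, so the labels could not be checked against the targeted genes.

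Gene names came from the authors' deposited table of regulated genes, which listed 26 symbols as up regulated and 76 as down regulated. ALDH1A1 and ALDH3A1 were both among the down regulated genes of the authors' deposited table. It gives no fold change, error or test and does not name the groups compared. Its directions are the authors' own and may rest on these same samples, so the authors' deposited table is no independent check. Of the 102 symbols, 78 were current symbols of the RefSeq gene table, 12 were older symbols with a single match and 12 had no single match.

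Among the 34 members of a fixed list of NF-kB targets and inflammatory cytokines, the authors' deposited table placed 4 down and 1 up. Those listed as down were the chemokine genes CCL20, CXCL2 and CXCL3 and the apoptosis inhibitor BIRC3. The one listed as up in the authors' deposited table was IL11, a cytokine of the interleukin 6 family. No difference was detected between the split of this list and that of the rest of the authors' deposited table (Fisher's exact test, two-sided, p = 1, adjusted p = 1). With 5 members listed and most of that table down, the test could hardly have detected a leaning towards down. BIRC3 and BCL2A1, a BCL2-family survival gene, were the 2 members of the apoptosis list in the authors' deposited table, both listed as down, too few to test. SOCS3, a feedback inhibitor of cytokine signalling, and SQSTM1, which encodes the autophagy receptor p62, were also down in the authors' deposited table. They lie outside the fixed lists and were chosen after the table was seen.

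Genes of the TGF-beta pathway were listed in both directions. From the fixed TGF-beta list, the authors' deposited table had TGFBR1, the type I receptor, and FST, which encodes the activin antagonist follistatin, as up regulated. It had the ligand gene TGFB2 and ID2, an inhibitor of helix-loop-helix transcription factors, as down regulated (Fisher's exact test between the parts of the authors' deposited table, two-sided, p = 0.268, adjusted p = 0.536 over the 2 lists with at least 3 members). With 4 members listed, the TGF-beta test too could hardly have detected a leaning towards down. Also listed as down in the authors' deposited table, and chosen after it was seen, were the co-receptor gene TGFBR3, the signal transducer SMAD1 and the inhibin subunit gene INHBB.

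In the authors' deposited table FN1 (fibronectin) and CLDN2 (a tight junction claudin) were up, while ITGB5 (integrin beta 5) and VCL (vinculin, a focal adhesion protein) were down. The authors' deposited table had HMOX1, which encodes haem oxygenase and is an NRF2 target, as up, and TKT, the transketolase of the pentose phosphate pathway and another member of the NRF2 list, as down. FADS2, a fatty acid desaturase, was up in the authors' deposited table, while ASNS (asparagine synthetase, an ATF4 target) and CCNG1 (cyclin G1, a p53 target) were down. Of the 35 fixed lists, 14 had a member in the authors' deposited table, and the other 21 had none. These 21 included retinoid metabolism and retinoic acid response, mitosis, interferon-stimulated genes and the markers of haematopoietic, fibroblast and endothelial cells.

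By chromosome, the authors' deposited table placed 6 down regulated genes on the Y chromosome and 0 up regulated genes. The 6 genes of the authors' deposited table were DDX3Y, USP9Y, UTY, RPS4Y1, EIF1AY and SMCY, the last now named KDM5D. The share on Y was compared between its 25 up and 73 down genes with a readable band (Fisher's exact test, two-sided, p = 0.333). All 6 down is the most extreme split in that direction, so this test could not have detected a leaning of Y genes towards down. Whether the Y chromosome holds more of the listed genes than its size would give was not tested. In the authors' deposited table chromosomes 4 and 12 also held 6 down and 0 up genes each, and chromosome 11 held 4 up and 1 down. These counts do not allow for the number of genes on each chromosome. The band given in the authors' deposited table named another chromosome than RefSeq for 2 genes, ID2 and EMP1. EMP1 is 1 of the 6 counted on chromosome 4 by its band, and RefSeq places it on chromosome 12.

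Arrays separated by group, and GFP siRNA replicate 3 lay apart from the other 3 arrays of its group. The first principal component of the 30351 probe sets held 68.1% of the variance and set the GFP siRNA arrays apart. The second held 15.3% and separated ALDH siRNA from wild type arrays. Pairs of wild type arrays correlated at Pearson's r between 0.988 and 0.993 across probe sets, and pairs of ALDH siRNA arrays at 0.970 to 0.982. GFP siRNA replicates 1, 2 and 4 correlated with each other at 0.992 to 0.996, whereas replicate 3 correlated with them at 0.947 to 0.961. The median SD within a group was 0.09 (log2) in wild type, 0.13 in ALDH siRNA and 0.11 in GFP siRNA cells.

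**Figure D1:**
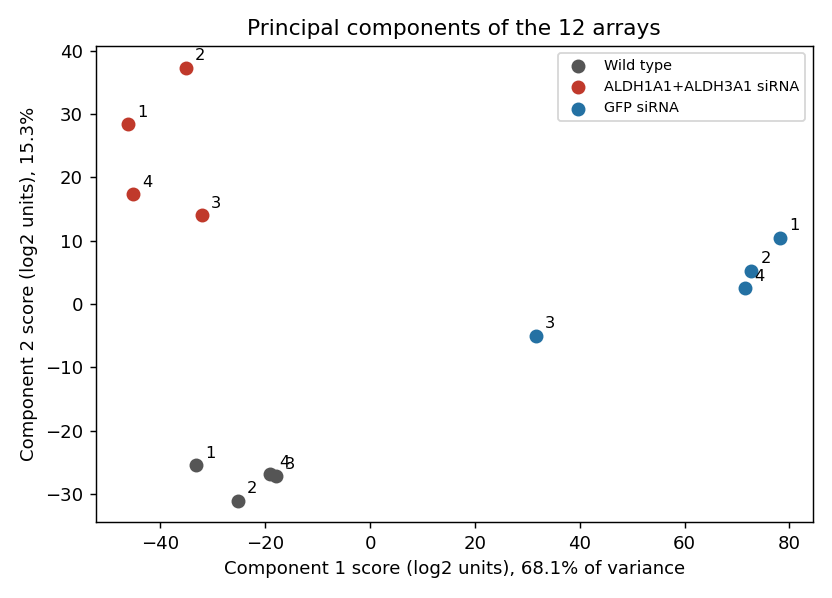
Scores of the 12 arrays on the first 2 principal components of the normalized log2 signal (log2 units); each point is an array, coloured by group and numbered by replicate. GFP siRNA replicates 1, 2 and 4 lie between 71.5 and 78.2 on component 1, replicate 3 lies at 31.7, and the other 8 arrays lie below 0.

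ALDH siRNA cells were first compared with the GFP siRNA control. Of 30351 probe sets, 20185 (66.5%) were called (limma, adjusted p under 0.05), 9939 higher and 10246 lower in ALDH siRNA cells. The median size of the called changes was 0.49 on the log2 scale, with a median standard error of 0.09. At 2-fold or more, 1904 were higher and 734 lower, and at 8-fold or more 65 were higher and 11 lower. The 4 ALDH siRNA arrays did not overlap the 4 GFP siRNA arrays in 16325 probe sets (53.8%), where chance alone gives 2.86%. The direction split followed the scaling. Without normalization 13422 were higher and 6251 lower, and with median centring 8186 were higher and 13170 lower. The median probe set differed by 0.13 without normalization and by -0.16 with median centring, against -0.03 after quantile normalization. With GFP siRNA replicate 3 as the only GFP array, the median change of these 20185 in the called direction went from 0.49 to 0.33 (log2). Fewer probe sets were called in that fit, which a single GFP array brings about in itself.

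**Figure D2:**
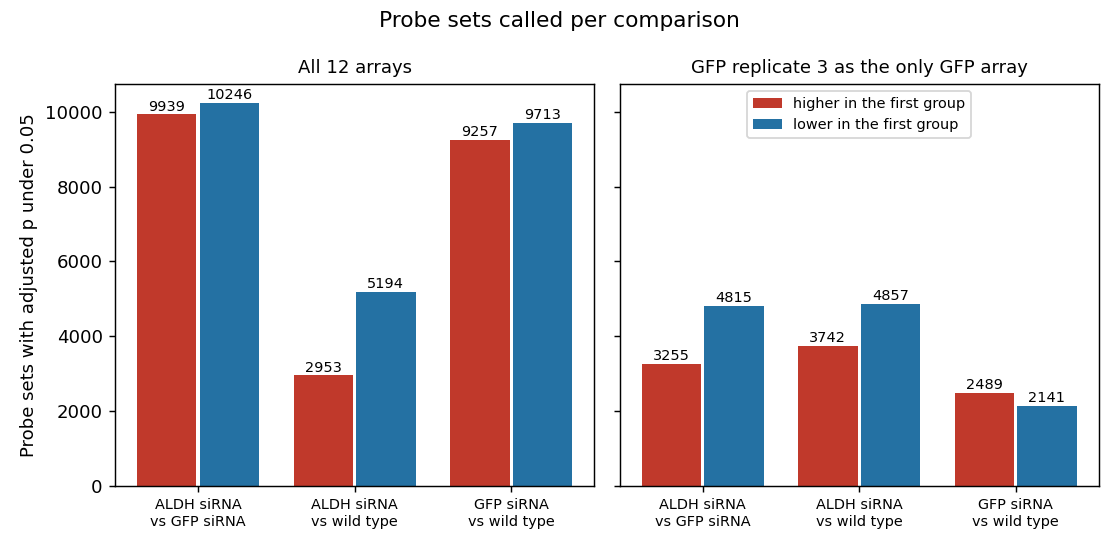
Number of probe sets with a limma adjusted p under 0.05 (vertical axis) in each comparison, with all 12 arrays (left) and with GFP siRNA replicate 3 as the only GFP array (right); bars give those higher (red) and lower (blue) in the group named first. Calls in ALDH siRNA against GFP siRNA go from 20185 to 8070, and those of GFP siRNA against wild type from 18970 to 4630.

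Against untransduced cells the ALDH siRNA group differed less, and more often downward. Effects of the ALDH siRNAs, the vectors, the clones and the processing of the arrays cannot be told apart in this comparison. The poly-A spike-in controls differed here too, at 175 in ALDH siRNA and 231 in wild type cells (exact permutation p = 0.0286, adjusted 0.0458). Of the 30351 probe sets, 8147 (26.8%) were called, 2953 higher and 5194 lower in ALDH siRNA cells (limma, adjusted p under 0.05). The median size of the called changes was 0.37 on the log2 scale. At 2-fold or more, 92 were higher and 275 lower, and at 8-fold or more 0 were higher and 6 lower. Under median centring 1370 were higher and 5919 lower. The higher calls numbered 1894 without wild type replicate 2 and 1965 without wild type replicate 4. An unmoderated unequal-variance test with the same adjustment called 3974, and leaving out probe sets ending in _x_at or _s_at left 4615 calls.

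GFP siRNA cells differed from wild type by nearly as many probe sets as they did from ALDH siRNA cells. This comparison involves no ALDH siRNA, but effects of the control vector, the clones and the processing of the arrays cannot be told apart in it. Here 18970 probe sets (62.5%) were called, 9257 higher and 9713 lower in GFP siRNA cells, with 435 higher and 1174 lower at 2-fold or more (limma, adjusted p under 0.05). At 8-fold or more, 2 were higher and 57 lower. In 12 of the called probe sets all 4 GFP siRNA arrays lay at the floor while wild type lay at least 8-fold above it, and in 0 the reverse held. The direction split depended on the settings. Without normalization 5358 were higher and 13301 lower, with median centring 10856 were higher and 8563 lower, and without a filter 15110 were higher and 12708 lower. The unmoderated unequal-variance test gave 8075 higher and 6313 lower. The calls at 2-fold or more, 1609 in all, numbered 2620 without GFP siRNA replicate 3, 2458 with array weights and 2569 without normalization. With GFP siRNA replicate 3 as the only GFP array fewer were called, which a single GFP array brings about in itself.

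Changes shared against both controls were mostly falls. Features of the clones or of the array processing particular to the ALDH siRNA arrays would be shared in the same way as effects of the siRNAs. In 5173 probe sets ALDH siRNA cells were called the same way against GFP siRNA and wild type, 1466 higher and 3707 lower, and 796 were called in opposite directions. Independent lists of these lengths would share 2720. The 20 simulations of unchanged groups sharing the ALDH siRNA arrays gave at most 0, but with nothing changed the adjustment leaves few or no calls in either comparison. They thus give no reference for the overlap that the shared arrays add to real calls. With the ALDH siRNA arrays halved, so that each comparison used its own 2, between 2928 and 4622 were shared. The fold changes of the 2 comparisons correlated across probe sets at r = 0.473, where unchanged groups gave 0.501. Their covariance was 0.0898 against 0.00761 in unchanged groups, and between 0.0654 and 0.0982 with the arrays halved. Probe sets are not independent replicates. At 2-fold or more against both controls, 56 probe sets were higher and 132 lower. In 4113 of the shared calls the 4 ALDH siRNA arrays lay beyond all 8 control arrays, 1176 above and 2937 below. The split of the shared calls moved to 1821 higher and 2730 lower without normalization, and to 649 higher and 4587 lower with median centring. It was 2620 higher and 3787 lower without GFP siRNA replicate 3, and 2568 higher and 4366 lower with array weights.

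The 2-fold calls against GFP siRNA went largely with shifts of GFP siRNA from wild type cells. Of the 1904 higher probe sets, 242 were also called higher against wild type and 1877 were called lower in GFP siRNA than in wild type cells. Their median change was 1.21 against GFP siRNA and 0.22 against wild type (log2). Of the 734 lower probe sets, 533 were also called lower against wild type and 626 were called higher in GFP siRNA than in wild type cells, and the median change was -1.26 against GFP siRNA and -0.56 against wild type. These counts share arrays between comparisons, and the difference between directions was not tested. With GFP siRNA replicate 3 as the only GFP array, the median size over all 2638 went from 1.219 to 0.785 (log2).

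The probe sets picked by the fixed rule were called the same way against both controls by construction, which leaves out most of the 1904 higher ones. The rise ranked first was probe set 217564_s_at, at 3705 in ALDH siRNA cells (geometric mean of normalized signal; log2 11.86 ± 0.18, SD, n = 4) and 2166 in wild type cells (11.08 ± 0.06, SD, n = 4). In GFP siRNA cells 3 of its 4 arrays lay at the floor of 32, so that ALDH siRNA cells were at least 116-fold higher (limma adjusted p = 4.19e-14), and against wild type they were 1.71-fold higher (limma adjusted p = 2.48e-05). Probe set 204920_at was at 5927 in ALDH siRNA, 3742 in wild type and 55.9 in GFP siRNA cells, a log2 difference of 6.73 ± 0.08 (SE) against GFP siRNA and 0.66 ± 0.08 (SE) against wild type. The fall ranked first was probe set 204409_s_at, at the floor on all 4 ALDH siRNA arrays, at 647 in GFP siRNA and at 273 in wild type cells. It was at least 20.2-fold lower than in GFP siRNA and at least 8.54-fold lower than in wild type cells (limma adjusted p = 4.19e-14 and 3.7e-12). Probe set 201909_at was at 294 in ALDH siRNA, 4631 in GFP siRNA and 2597 in wild type cells, 15.7-fold and 8.82-fold lower. Of the 10 largest rises by the rule, 6 had a GFP siRNA array at the floor, and of the 10 largest falls 8 had an ALDH siRNA array at the floor, so these changes are lower bounds. Against wild type the 10 rises ranged from 0.28 to 2.34 (log2), and the 10 falls from 0.46 to 3.14 in size, with those at the floor entered at their lower bounds.

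Differences from wild type were wider for GFP siRNA than for ALDH siRNA cells at every signal level. Probe sets were ranked by mean signal into 10 bins of equal size. In bin 3 (mean signal 48.9 to 64.4) the SD over probe sets of the GFP siRNA minus wild type difference was 0.48 (log2), against 0.25 for ALDH siRNA minus wild type. In bin 10, the brightest, the values were 0.57 and 0.31. The first was 1.95 times the second in bin 3 and 1.84 times in bin 10, and between 1.43 and 2.08 times over the 10 bins. GFP siRNA replicate 3 showed 0.28 of the difference of replicates 1, 2 and 4 from wild type in bin 3 and 0.96 of it in bin 10 (slope through the origin, log2).

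**Figure D3:**
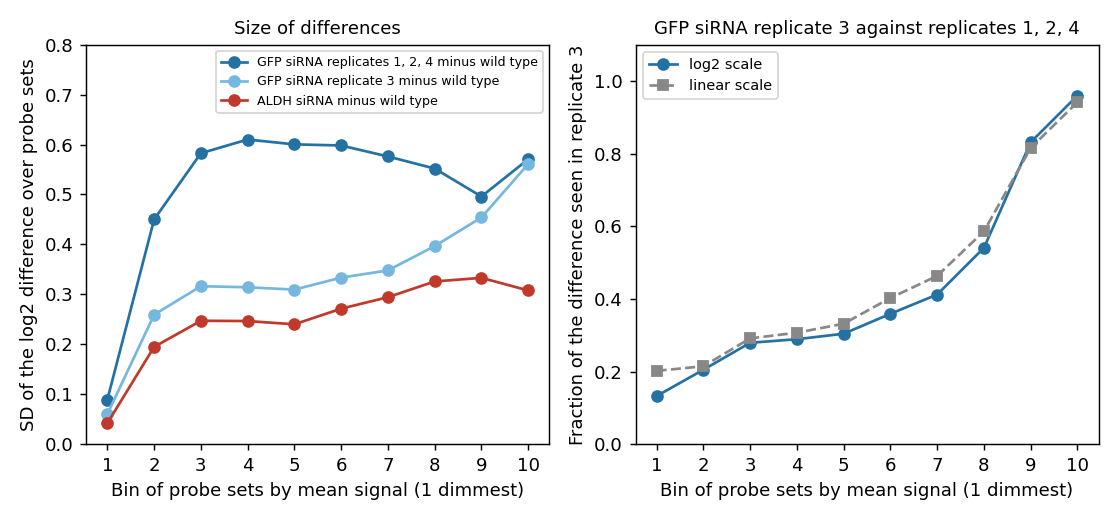
Left, SD over probe sets of the log2 difference from wild type, by bin of mean signal (1 dimmest, 10 brightest), for GFP siRNA replicates 1, 2 and 4, GFP siRNA replicate 3 and the ALDH siRNA group; right, the fraction of the difference of replicates 1, 2 and 4 from wild type that replicate 3 shows. Replicate 3 lies near replicates 1, 2 and 4 in bin 10, at 0.96 of their difference, and shows 0.28 of it in bin 3. The bins hold all probe sets, including those the filter left out.

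Several control readings, but not all, set the GFP siRNA arrays apart from both other groups. The middle HUMRGE control set, a ribosomal RNA control in the manufacturer's naming, read 7528 ± 2541 (SD, n = 4) in wild type, 7542 ± 1583 (SD, n = 4) in ALDH siRNA and 1679 ± 1816 (SD, n = 4) in GFP siRNA cells. ALDH siRNA against GFP siRNA gave an exact permutation p = 0.0286 (adjusted 0.0458), the smallest p that 4 against 4 arrays can give, and ALDH siRNA against wild type gave an exact p = 1. Poly-A spike-in controls, transcripts added to the RNA before labelling, had a geometric mean signal of 231 ± 25.7 (SD, n = 4) in wild type, 175 ± 26.0 (SD, n = 4) in ALDH siRNA and 102 ± 11.3 (SD, n = 4) in GFP siRNA cells. Each of these 3 differences had an exact permutation p = 0.0286 (adjusted 0.0458). The ratio of 3' to 5' signal of the HSAC07 control, a measure of RNA integrity and labelling, was 1.201 ± 0.0111 (SD, n = 4) in GFP siRNA cells and 1.32 ± 0.0918 (SD, n = 4) in ALDH siRNA cells (exact permutation p = 0.0286, adjusted 0.0458). The 3' control labelled HUMISGF3A was 1.42-fold higher in ALDH siRNA than in GFP siRNA cells (exact permutation p = 0.0286, adjusted 0.0458) and 1.01-fold that of wild type (exact permutation p = 0.829). The 3' to 5' ratio of the HUMGAPDH control was 1.15 in GFP siRNA, 1.21 in ALDH siRNA and 1.23 in wild type cells, and neither comparison with GFP siRNA passed (exact permutation p = 0.0571, adjusted 0.0806, for each). The hybridization spike-in controls did not differ detectably between ALDH siRNA and GFP siRNA cells (geometric means 1110 and 798, exact permutation p = 0.0857, adjusted 0.114) and were lower in GFP siRNA than in wild type cells (798 against 1268, exact permutation p = 0.0286, adjusted 0.0458). No label gives a processing batch.

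**Figure D4:**
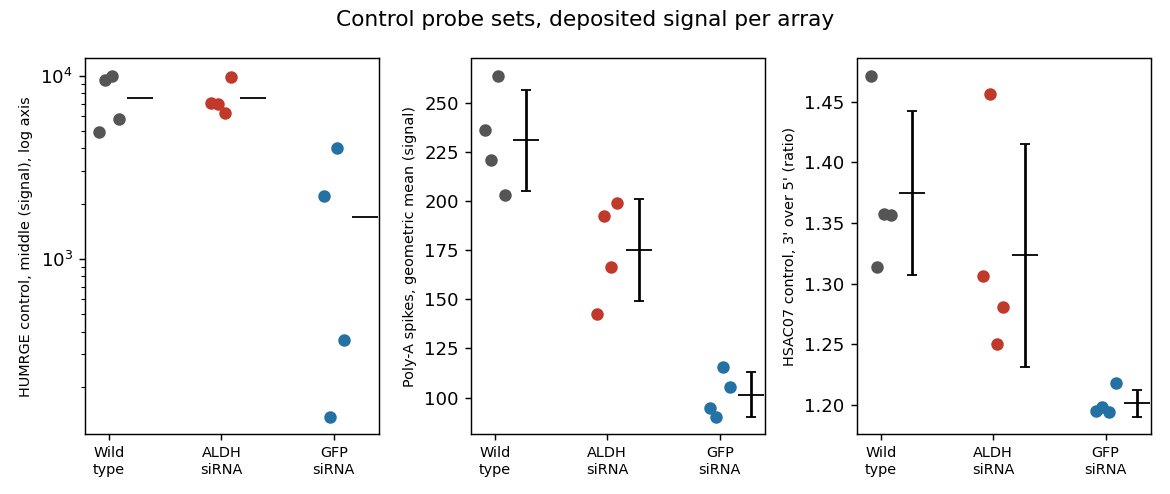
Deposited signal of the middle HUMRGE control (log axis), the geometric mean of the poly-A spike-in controls, and the 3' over 5' ratio of the HSAC07 control, per array; points are arrays, horizontal bars are group means, and vertical bars are SD (not drawn on the log axis). All 4 GFP siRNA arrays lie below the arrays of both other groups in each panel.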

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

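All tests in this part other than the splits of the arrays were chosen only after the result was seen.

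GFP siRNA replicates 1, 2 and 4 stood apart from replicate 3, whose mean correlation with its own group was 0.955 and whose median signal was 98.2, both far from the other 3 arrays. The tables argue against a difference in overall scale, since 88.2% of the distance between them was left after quantile normalization. They also argue against replicate 3 being a mixture of GFP siRNA and wild type RNA, which would give 1 fraction at every signal level. On the linear scale the fraction was 0.65 higher in bin 10 of mean signal, the brightest, than in bin 3. Further from the floor, it was 0.586 in bin 8 (mean signal 151 to 209), against 0.942 in bin 10. An array processing difference that moves dim probe sets as much as bright ones stays open. The GFP siRNA minus wild type SD was 1.95 times that of ALDH siRNA minus wild type in bin 3 and 1.84 times in bin 10. Such a processing difference would give similar ratios in both bins. A difference between clones could give them too, so the ratios do not favour either explanation. A biological difference between GFP siRNA clones stays open and untested, and no label gives a batch.

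The calls in ALDH siRNA against GFP siRNA carry the same pattern. Tested probe sets were split here into dim and bright at a mean signal of 160.8, not by bin. With replicate 3 as the only GFP array, the median change of the 10600 called dim probe sets kept 0.495 of its size. That of the 9585 called bright probe sets kept 0.903. This follows from the position of replicate 3 and does not decide what caused it, so an array processing difference and a difference between clones cannot be told apart by it.

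For each count the real split gave the most calls, but this cannot exclude chance. A share of 1 in 35 is the smallest that 35 splits can give. The other splits mix arrays of different groups, which widens the spread within each part and lowers the calls. Splits also cannot tell whether the arrays of a group are independent clones or share a batch. In ALDH siRNA against GFP siRNA, 1 of the 35 splits of the 8 arrays reached 20185 calls, the real one, and the highest other gave 6950. In GFP siRNA against wild type it was 1 of 35, with 18970 calls against at most 5644. In ALDH siRNA against wild type it was 1 of 35, with 8147 calls against at most 5. Of 100 splits of the 12 arrays, 1 reached the 5173 calls shared against both controls, and the highest other gave 0.

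Among 37 groups of 4 values tested for an array far from the rest, 6 stood out, where chance gives about 1 in 20. Besides the 2 values above, GFP siRNA replicate 4 had an HSAC07 3' over 5' ratio of 1.22, and GFP siRNA replicate 3 a HUMISGF3A 3' signal of 648. Probe set 201909_at was at 11.39 (log2) in wild type replicate 3 and at 12.25 in GFP siRNA replicate 4.

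Most control probe sets, which were left out of the fit across probe sets, had a higher mean in ALDH siRNA than in GFP siRNA cells. ALDH siRNA over GFP siRNA means were 9.21 for the 5' HUMRGE set, 4.49 for the middle HUMRGE set and 3.76 for the middle M27830 set. All 45 spike-in control sets had a higher mean in ALDH siRNA cells, from 1.14-fold to 2.29-fold. Of these, 3 were at least 2-fold higher without overlap.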

How the results depend on the processing

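The 4 counts kept within 1.5 times their reported value under most alternatives. Exceptions were the filter at the 75th percentile, with 10417 calls in ALDH siRNA against GFP siRNA and 9999 in GFP siRNA against wild type, where fewer probe sets were tested. Leaving out probe sets ending in _x_at or _s_at, which also left fewer to test, gave 4615 in ALDH siRNA against wild type and 3044 shared against both controls. Welch's test gave 3974 in ALDH siRNA against wild type and 2593 shared against both controls, and the cause was not tested. With GFP siRNA replicates 1, 2 and 4 left out, a setting chosen after seeing the data that assumes the lone array varies like the other groups, ALDH siRNA against GFP siRNA gave 8070 and GFP siRNA against wild type 4630, and 3522 were shared against both controls, of which 3154 were among the 5173. Leaving out 1 array gave 17916 to 20656 calls in ALDH siRNA against GFP siRNA, 5983 to 8826 against wild type, 15852 to 19703 in GFP siRNA against wild type and 3946 to 6407 shared. The replicate block, with clone numbers that share only a number, gave 19621, 7158, 18252 and 4661 in the same order, and 2 of the 12 arrays compared correlated best with their own number. A direction or 2-fold count also moved by over 1.5 times in fits without GFP siRNA replicate 3, with array weights and without wild type replicate 2 or 4, as given with the results. Averaging ALDH siRNA replicates 1 and 2 gave 19795, 6983, 19439 and 4449. Without a filter, ALDH siRNA against GFP siRNA reached 30159. Against GFP siRNA, the 4 named probe sets kept their direction and call in every alternative fit in which they were examined. They were not examined in the fits without a wild type array, and their changes against wild type were not examined under any alternative. With no gene names, the alternatives for the targeted genes, gene lists, genes per chromosome and 1 probe set per gene were not run. A floor of 32 limits what can be said of dim probe sets.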

Other observations

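All tests in this part were chosen only after the result was seen. Of the 5173 probe sets in which ALDH siRNA cells differed the same way from both controls, 2783 were not called between GFP siRNA and wild type cells and 2390 were. Over all 30351 probe sets 18970 (62.5%) were called there. Requiring the same direction against both controls itself favours probe sets in which the controls agree, so the split has no reference here. In ALDH siRNA against GFP siRNA, 11 called probe sets had all 4 GFP siRNA arrays at the floor with ALDH siRNA cells at least 8-fold above it, and 4 had the reverse. In ALDH siRNA against wild type, 2 had all 4 ALDH siRNA arrays at the floor and 0 the reverse.

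Fold changes of ALDH siRNA against GFP siRNA and of GFP siRNA against wild type correlated across probe sets at -0.854, where unchanged groups sharing the GFP siRNA arrays gave -0.502. Their covariance was -0.275 against -0.00763 in unchanged groups.

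The titles of ALDH siRNA replicates 1 and 2 (1A and 1B) raise the hypothesis that they are 1 clone sampled 2 times. The SD of their log2 difference was 0.23, rank 2 of the 6 pairs in the group, and the closest pair, replicates 3 and 4, also had 0.23. Whether the pair is 1 clone cannot be told apart from 2 clones by these distances, since the closest pairs differ too little.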
